A study of Rattus norvegicus with 8 samples.

How the data were processed

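Gene expression was measured by 10x Visium spatial transcriptomics in 8 fresh-frozen sections of rat eyes, 2 from each of 4 eyes. Both treatments had 2 eyes: an anterior chamber hydrogel that raises the intraocular pressure, collected at 7 days, and PBS. The values are raw UMI counts per gene and spot, deposited after processing by the authors with Space Ranger 1.1.0, per the file headers, on the Rnor_6.0 build, per the labels. The deposited counts hold 32883 gene rows with 28913 distinct names and only spots under tissue, without positions. Gene names were used as the files give them, and 726 of 749 listed genes matched a name in the files, 6 of them through a synonym of a gene table of the GRCr8 assembly. UMI totals per eye were 8628200 to 19459000.0. Lower limits use a floor of 3 counts over the group, and intervals of ratios are 95% exact intervals of the counts. Both cover counting error only.

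Spots were grouped by RNA with Python 3.11.15, numpy 2.4.6 and scanpy 1.11.5. Spot totals were scaled to 10000 and log-transformed, 2000 variable genes were chosen within sections, and 30 principal components with 15 neighbours were clustered by Leiden (igraph 0.11.9, resolution 0.8). A cluster took the name of a marker list when at least 3 of its members were among the 50 genes with the largest fold over the other spots (pseudocount 20 CPM), at least 2 were among the leading 10 and at most 2 members of other tissues' lists were among those 10. The conditions on the leading 10 genes were set after the clusters were seen. Clusters with the same name were joined, and other clusters are named by their leading genes. Regions with at least 10 spots in each of the 4 eyes were tested. Spots hold several cells, so a region is a group of spots and not a cell type.

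Counts were summed per eye, in whole sections and in each region, and compared with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr with a minimum of 10 counts, quasi-likelihood test, Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The standard error is the fold change divided by the square root of the F statistic. Named genes were chosen by a rule set before the data were examined: the 12 called genes with the largest changes in each direction for whole sections and the RGC region, and 5 for the others, among genes with a mean log2 CPM of at least 4 whose eyes did not overlap between groups, leaving out genes that define the region. Of the 3 splits of 4 eyes into 2 and 2, 1 leaves the groups without overlap for any gene, so this condition is weak by itself. Example members of lists are among the 4 called members with the smallest p. Some genes that these rules pick are not reported here; they stay in all tests and counts. The lists were 27 marker and 22 functional lists, tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation, with cameraPR and with fry. Genes that define a region were left out of that region's lists, a choice made after values were seen. Differences between regions were tested as an interaction in edgeR with the eye as a block, and shares of spots with an exact two-sided permutation test.

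Alternatives were DESeq2 1.42.0, library size and upper quartile factors, genes over 1% of the counts left out, no filter and a filter of 50 counts in 2 eyes, sections as samples with and without a block, sections with the same number only, spots with at least 500 genes, the mean of spots (limma on log2 of CPM + 1), the 7 regions summed at equal shares, other clusterings (resolutions 0.4 and 1.6, 292 marker genes only, section means removed), at least 30 spots per eye, and leaving out each eye and each section. Counts thinned to the shallowest eye, the removal of free RNA at 2 rates, the 7 regions summed at their own shares and shares with section means removed were added after the data were seen. In other clusterings, a cluster was taken for the region that held the majority of its spots. The fit was tested on simulated data at the depth of each comparison: of 200 changed genes, 38.8% of those changed 2-fold and 90.9% of those changed 4-fold were called in whole sections (13420 genes), and 49.2% and 93.9% in the RGC region (9135 genes). Across comparisons 0 to 7.58% of simulated calls were false. Camera called 2 of 2 shifted and 0 of the other lists, which did not test correlated genes. Spots outside tested regions entered whole-section sums only. Protein levels and pressures were not analysed. Figures used matplotlib 3.10.9.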

Results

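Sections of whole rat eyes were profiled by spatial transcriptomics, in which each spot of a slide captures the polyadenylated RNA of the tissue above it. The samples were 8 sections of 10 µm, 2 from each eye. Of the 4 eyes, 2 were given an anterior chamber hydrogel to raise the intraocular pressure, collected after 7 days, and 2 PBS. The sections passed through the optic nerve head and lay at least 20 µm apart. The eye was the replicate, so every comparison below is 2 hydrogel eyes against 2 PBS eyes. The labels do not say whether the 2 hydrogel eyes came from different animals, and name no slide or sequencing run, so a batch and the treatment cannot be told apart. They give no collection day for the PBS eyes, so the time after injection cannot be told apart from the treatment either. They name no strain, so a difference in stock between the groups stays open. Hydrogel sections held 943 to 1072 spots and 7699986 to 10050254 UMIs, and PBS sections held 741 to 840 spots and 3954001 to 5221463 UMIs. The median spot of a section held 3569 to 6236 UMIs. A count of 3 in a section is 0.3 to 0.76 CPM (counts scaled to a common library total). Ratios have exact counting intervals (CI). Fold changes are log2 of hydrogel over PBS ± standard error (n = 2 eyes per group). A gene is called at an adjusted p below 0.05. Where leaving out 1 eye or section ended a call, that adjusted p follows in parentheses. For calls that any alternative ended, brackets give the adjusted p range over alternatives that tested the gene. Not all tested every gene.

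Clustering of the 7198 spots by RNA gave 21 groups, named by leading genes. Ganglion cell genes such as Stmn2, Nefl and Sncg led 2 of them, joined as the RGC region. Cluster 4 held most of its hydrogel and cluster 16 most of its PBS spots, so its tests largely compare these 2. Rpe65 and Ttr, of the visual cycle and retinol transport, led the RPE region, Gng13 and Neurod4 the bipolar region, Ppef2 and Pde6b the rod region, and Mbp the myelin region. Nefh, Kif5a and Gfap led cluster 14, and Igfbp6 and haemoglobin genes led cluster 7. Only these 7 regions had at least 10 spots in each eye and were compared. They held 46.9% of all spots, less in hydrogel than PBS eyes. The other groups, except skeletal muscle (Mylpf and Myh4), lay almost entirely in the eyes of 1 treatment. The interferon-gamma targets Ubd, Cxcl10 and Cxcl11 led cluster 1, with 15.7% of hydrogel and 0% of PBS spots. Rod genes together with Rpe65 led cluster 15, with 0.0744% of hydrogel and 16.1% of PBS spots. The cartilage and tendon matrix genes Chad and Cilp2 led the fibroblast and sclera group, with 13.8% of hydrogel and 0.158% of PBS spots, and its 50 leading genes included 8 rod genes. Whether such groups, or clusters 4 and 16, are tissue that the other sections lack or the same with changed RNA stays open.

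**Figure D1:**
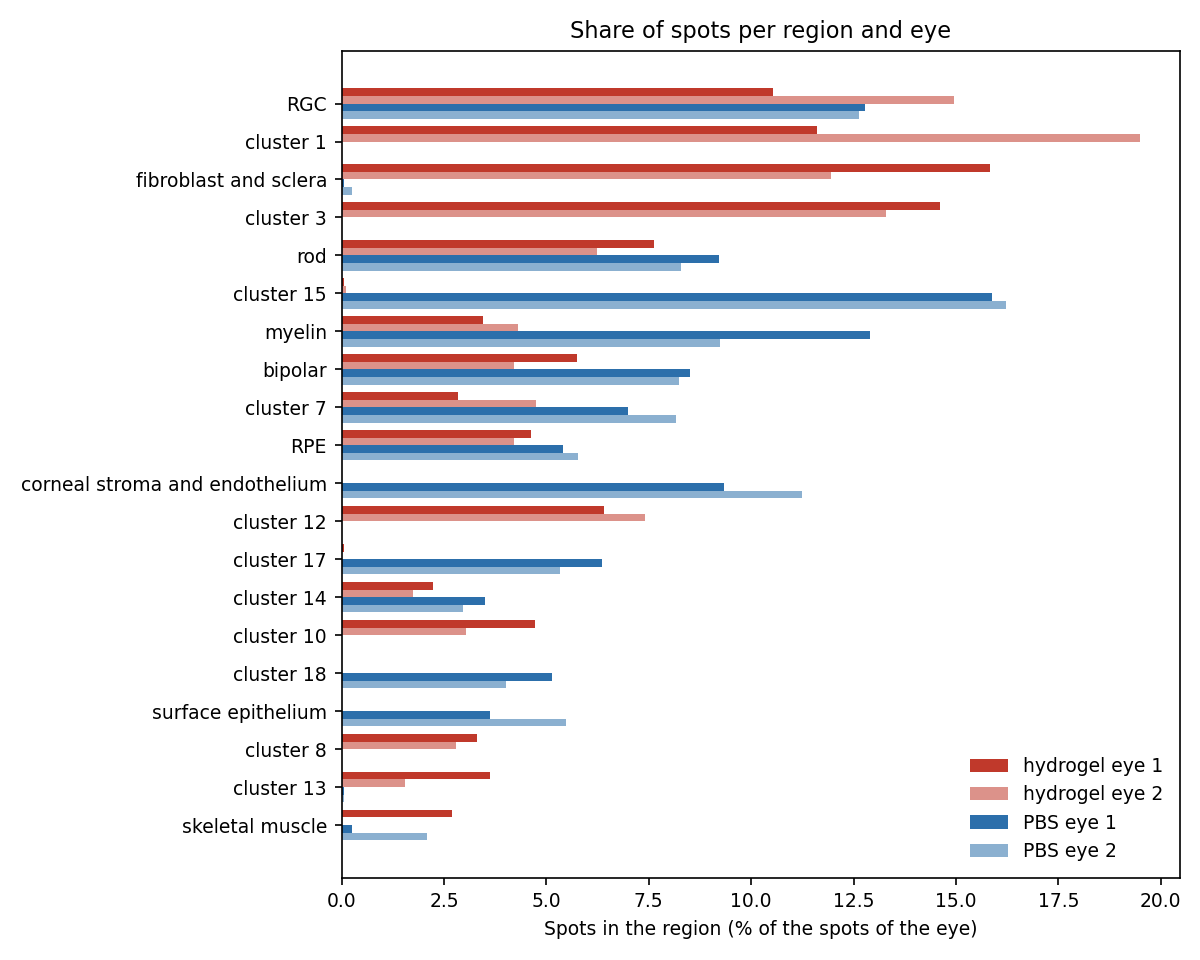
Percent of each eye's spots in each region or cluster, with 1 bar per eye (red: hydrogel, blue: PBS, n = 2 eyes per group). Cluster 1 reached 19.5% of the spots in hydrogel eye 2 and 0% in both PBS eyes.

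Most sections resembled the other section of their eye more than those of other eyes. The biological coefficient of variation of gene counts was 11.8% between the 2 sections of an eye and 19.3% between eyes of a group (21.2% for hydrogel and 17.0% for PBS). Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.981 to 0.987 between sections of an eye, 0.965 to 0.976 between eyes of a group and 0.843 to 0.906 between hydrogel and PBS sections. By chi-square per degree of freedom, however, the second section of PBS eye 1 lay nearer to the first of PBS eye 2 (8.05) than the sections of PBS eye 2 to each other (8.70). Ribosomal protein genes took 8.84 to 10.4% of the UMIs of hydrogel sections and 6.46 to 6.82% of those of PBS sections.

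In whole sections, immune genes were among the largest increases. Cd8b, a co-receptor of cytotoxic T cells, had no counts in PBS eyes and was at least 213-fold higher in hydrogel eyes (floor of 3 counts over the PBS group), and its partner Cd8a rose by 6.87 ± 0.24 (adjusted p = 3.59e-04). The ubiquitin-like modifier Ubd rose by 11.47 ± 0.79 (1494 ± 913 against 0.593 ± 0.511 CPM). The T-cell attractants Cxcl9 (7.2 ± 0.46) and Cxcl11 (8.88 ± 0.75), the T-cell adhesion receptor Cd2 (7.14 ± 0.3) and the MHC class II gene RT1-Bb (7.73 ± 0.37) rose as well. Other named increases were the phagocyte lectin Fcnb (8.1 ± 0.38), the hexokinase Hk3 (7.36 ± 0.66), the cystatin Cst7 (7.23 ± 0.33) and the serpin LOC299282 (7.45 ± 0.9). Acod1, which makes itaconate in macrophages, had 1 PBS count (ratio 788, 95% CI 141 to 31150), and the MHC II adaptor Scimp had 3 (ratio 260.4, 95% CI 88.9 to 1264). In all, 2772 of 13437 genes tested were called, 1913 higher and 859 lower, and 1881 of them changed at least 2-fold. Without hydrogel eye 2 the count was 1137 and without PBS eye 1 it was 1489. Reads of RT1 genes, which have near-identical copies, can be assigned to the wrong copy. Acod1 [2.03e-06 to 0.0853] lost its call in other settings.

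Immune cell lists rose. Medians after lists are of the log2 fold changes of all tested members, and the adjusted p of camera at a preset correlation is followed by that with an estimated correlation. List alone marks calls with p adjusted over the list alone. Of the macrophage and microglia genes, among them Ptprc, Laptm5 and Tyrobp (4.9 ± 0.27, 4.12 ± 0.22 and 3.26 ± 0.19), 16 of 17 rose and 1 did not pass (list alone: 17 higher); median 3.05 (camera adjusted p = 2.84e-10, estimated 0.593). Cd3e and Cd3d, parts of the T-cell receptor, rose by 6.51 ± 0.23 and 6.54 ± 0.26. Of the lymphocyte list all 6 rose (list alone: 6 higher); median 5.89 (camera adjusted p = 1.65e-07, estimated 0.593). The neutrophil genes S100a8 (2.8 ± 0.29), S100a9 (3.76 ± 0.89) and Csf3r (4.28 ± 0.52) made up the tested part of their list, of which all 3 rose (list alone: 3 higher); median 3.76 (camera adjusted p = 0.0129, estimated 0.593). S100a9 lost its call without hydrogel eye 2 (0.101) [4.13e-04 to 0.101]. Csf3r [2.35e-12 to 0.122] lost its call in other settings.

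Antigen presentation and inflammatory signalling rose alike. Of the MHC class II list, all 8 rose (list alone: 8 higher); median 4.53 (camera adjusted p = 1.65e-07, estimated 0.593). Its members RT1-Ba and RT1-Db1 rose by 4.75 ± 0.23 and 4.52 ± 0.24. Of the MHC class I and immunoproteasome list, all 13 rose (list alone: 13 higher), with RT1-A1 (4.16 ± 0.27); median 2.74 (camera adjusted p = 8.70e-09, estimated 0.593). The proteasome subunit Psmb9 of that list rose by 3.64 ± 0.22. Among interferon response genes, where the GTPase Gbp2 rose by 4.65 ± 0.37, 18 of 19 rose and 1 did not pass (list alone: 18 higher), with the antiviral Ifit2 (1.59 ± 0.16); median 1.53 (camera adjusted p = 1.27e-08, estimated 0.593). Complement genes included C1qc (3.05 ± 0.23) and the C1 inhibitor Serping1 (2.54 ± 0.22), and 11 of 16 rose and 5 did not pass (list alone: 12 higher); median 2.73 (camera adjusted p = 3.66e-06, estimated 0.593). Of the cytokine, chemokine and adhesion list, with Il1b at 5.02 ± 0.26, Ccl7 at 5.52 ± 0.44 and Icam1 at 2.59 ± 0.19, 17 of 21 rose, 1 fell and 3 did not pass (list alone: 18 higher and 1 lower); median 2.53 (camera adjusted p = 1.95e-08, estimated 0.593). Replication genes such as Mcm3 (1.89 ± 0.26) and Mcm5 (1.86 ± 0.29) rose. Of the cell cycle list 15 of 16 rose and 1 did not pass (list alone: 16 higher); median 1.69 (camera adjusted p = 3.02e-06, estimated 0.619). Ifit2 [2.80e-13 to 0.05005] and Mcm3 [1.90e-08 to 0.123] lost calls in other settings.

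Genes of the lens, the ocular surface and myelin were among those that fell. The lens crystallins Cryga (-3.57 ± 0.36), Crygb (-3.36 ± 0.66) and Crygd (-3.17 ± 0.76) were lower, as were the epithelial genes Slurp1 (-2.77 ± 0.54, 157 ± 99.5 against 1211 ± 629 CPM) and S100g (-3.2 ± 0.41). Tnnc1, a leading gene of a corneal group found in PBS eyes only, fell by 2.34 ± 0.37, and LOC361016 stood at -2.18 ± 0.46. Myelin genes fell: Mog by 2.47 ± 0.5, Ugt8 by 2.55 ± 0.46 and Opalin by 2.21 ± 0.53. The myelin region held 3.89% of hydrogel and 11.1% of PBS spots (14.0 and 5% in the sections of PBS eye 2). The fall itself can lower this share. The alpha-globin copy Hba-a3 stood at -6.52 ± 0.38. Gamma crystallins and alpha globins have near-identical copies, so the copy named is uncertain. Crygb lost its call without hydrogel eye 1 section 2 (0.0595) [7.37e-05 to 0.0595]. Crygd lost its call without hydrogel eye 1 section 2 (0.0916) [4.10e-04 to 0.0916]. LOC361016 lost its call without hydrogel eye 2 (0.0707) and PBS eye 2 section 1 (0.0536) [6.39e-06 to 0.498]. Mog lost its call without hydrogel eye 2 (0.0716) [3.02e-07 to 0.348]. Ugt8 lost its call without hydrogel eye 2 (0.0553) [2.10e-08 to 0.161]. Opalin lost its call without hydrogel eye 1 (0.0552), hydrogel eye 2 (0.115), hydrogel eye 1 section 1 (0.0573) and PBS eye 2 section 1 (0.0790) [2.31e-05 to 0.679]. S100g [1.16e-17 to 0.0506] and Tnnc1 [4.52e-10 to 0.0787] lost calls in other settings.

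Ganglion cell and myelin markers fell in whole sections, with fewer of other retinal cells. Cluster 1 added 3970111 and 7283933 UMIs to hydrogel eyes only, so dilution of these markers by it stays open. The surface protein Thy1 (-1.56 ± 0.19) and the neurofilaments Nefm (-1.31 ± 0.15) and Nefh (-1.46 ± 0.19) were lower. Of the ganglion cell list 14 of 15 fell and 1 did not pass (list alone: 14 lower); median -1.19 (camera adjusted p = 2.76e-07, estimated 0.593). Of the myelin list, which adds Mbp (-1.95 ± 0.32), 10 of 14 fell and 4 did not pass (list alone: 11 lower); median -1.88 (camera adjusted p = 3.36e-05, estimated 0.593). Of the amacrine list, with the calcium buffer Calb2 at -1.34 ± 0.22, 7 of 11 fell and 4 did not pass (list alone: 10 lower), with the GABA-making Gad2 (-1.15 ± 0.22); median -0.98 (camera adjusted p = 6.28e-05, estimated 0.593). Of the synapse list 1 of 22 rose, 9 fell and 12 did not pass (list alone: 1 higher and 15 lower), with the complexin Cplx2 (-1.38 ± 0.25) and the active zone protein Bsn (-1.08 ± 0.21); median -0.9 (camera adjusted p = 3.66e-06, estimated 0.593). Of the rod list 1 of 15 fell and 14 did not pass (list alone: none); median -0.72 (camera adjusted p = 0.00140, estimated 0.637). The 1 call was the phosphodiesterase subunit Pde6g (-1.79 ± 0.47). Of the bipolar list 2 of 13 fell and 11 did not pass (list alone: 1 lower), with the transcription factor Isl1 (-1.24 ± 0.26) and the carbonic anhydrase relative Car8 (-0.83 ± 0.22) called; median -0.63 (camera adjusted p = 0.00410, estimated 0.619). In the sum of the 7 regions Car8 stood at 0.09, and 0.12 at equal region shares. Of the astrocyte list 3 of 6 fell and 3 did not pass (list alone: 4 lower), with the aldolase Aldoc (-0.9 ± 0.21); median -0.89 (camera adjusted p = 0.0166, estimated 0.593). In that sum the bipolar, astrocyte and rod medians were 0.1, -0.02 and 9.62e-04 (camera adjusted p = 0.814, 0.947 and 0.947), and at equal shares 0.13, 0.41 and -0.12 (0.438, 0.203 and 0.470). Gad2 lost its call without hydrogel eye 2 (0.0646) and PBS eye 1 (0.0550) [2.60e-04 to 0.443]. Cplx2 lost its call without hydrogel eye 2 (0.0624) and PBS eye 1 (0.0547) [3.94e-04 to 0.342]. Bsn lost its call without hydrogel eye 2 (0.0654) and PBS eye 1 (0.0695) [4.14e-04 to 0.532]. Pde6g lost its call without hydrogel eye 1 (0.0640), hydrogel eye 2 (0.145), PBS eye 2 (0.0742), hydrogel eye 1 section 2 (0.0508), hydrogel eye 2 section 1 (0.0792) and PBS eye 1 section 2 (0.101) [1.68e-04 to 0.663]. Isl1 lost its call without hydrogel eye 2 (0.0619) and PBS eye 1 (0.0559) [5.55e-04 to 0.272]. Car8 lost its call without hydrogel eye 2 (0.148), PBS eye 1 (0.137), PBS eye 2 (0.0527), hydrogel eye 1 section 1 (0.0684), hydrogel eye 2 section 2 (0.0575) and PBS eye 2 section 1 (0.0701) [0.00234 to 0.863]. Aldoc lost its call without hydrogel eye 2 (0.111) and PBS eye 1 (0.125) [7.18e-04 to 0.927]. Thy1 [2.05e-08 to 0.248], Nefm [2.99e-08 to 0.417], Nefh [1.37e-09 to 0.150], Mbp [2.48e-09 to 0.480] and Calb2 [6.48e-07 to 0.228] lost calls in other settings.

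Some genes of the lens, the surface and other tissues changed as well. Of the lens list, 5 of 16 fell and 11 did not pass (list alone: 6 lower), with the crystallin Crygf (-3.95 ± 0.67); median -1.78 (camera adjusted p = 3.36e-05, estimated 0.593). Of the surface epithelium list, 2 of 15 fell and 13 did not pass (list alone: 1 higher and 4 lower), with the keratin Krt4 (-1.72 ± 0.25) and the keratin Krt1 (-1.3 ± 0.32) called; median -0.53 (camera adjusted p = 0.0339, estimated 0.684). Of the corneal stroma and endothelium list, with the borate and proton carrier Slc4a11 at -2.02 ± 0.37, 3 of 6 fell and 3 did not pass (list alone: 4 lower), with the retinal dehydrogenase Aldh1a1 (-1.82 ± 0.35). Of the meninges list, with Ptgds, which makes prostaglandin D2, at -1.38 ± 0.21, 4 of 6 fell and 2 did not pass (list alone: 4 lower), with the anion carrier Slc22a6 (-2.22 ± 0.36); median -0.95 (camera adjusted p = 0.00662, estimated 0.593). Of the melanocyte list, 1 of 5 fell and 4 did not pass (list alone: 4 lower), with the melanosome protein Pmel (-1.32 ± 0.3) called; median -0.64 (camera adjusted p = 0.0295, estimated 0.619). Of the fibroblast and sclera list, with the receptor Pdgfra at 1.33 ± 0.21, 5 of 14 rose, 1 fell and 8 did not pass (list alone: 6 higher and 1 lower), with the matrix protein Comp (2.46 ± 0.52). In the sum of the 7 regions Pdgfra stood at -0.02. Of the RPE list, 1 of 9 rose, 1 fell and 7 did not pass (list alone: 1 higher and 6 lower), with the chloride channel Best1 (1.51 ± 0.29) and the isomerase Rpe65 (-2.03 ± 0.43) called. Of the ciliary body and iris list, 1 of 7 rose, 3 fell and 3 did not pass (list alone: 1 higher and 4 lower), with the water channel Aqp1 (0.83 ± 0.14) and the protease inhibitor Wfdc1 (-0.95 ± 0.17). Crygf lost its call without hydrogel eye 2 (0.0515) [6.75e-09 to 0.0924]. Krt4 lost its call without hydrogel eye 2 section 1 (0.0508) [5.98e-07 to 0.114]. Krt1 lost its call without hydrogel eye 1 (0.0690), hydrogel eye 2 (0.167), PBS eye 1 (0.0908), PBS eye 2 (0.115), hydrogel eye 1 section 1 (0.0508), hydrogel eye 2 section 1 (0.0504), PBS eye 1 section 2 (0.0581) and PBS eye 2 section 2 (0.0682) [0.00239 to 0.929]. Pmel lost its call without hydrogel eye 2 (0.0859) and PBS eye 1 (0.0676) [6.81e-05 to 0.101]. Comp lost its call without hydrogel eye 2 (0.0579) [3.61e-06 to 0.0889]. Best1 lost its call without hydrogel eye 2 (0.0587) and hydrogel eye 1 section 2 (0.152) [2.67e-04 to 0.170]. Rpe65 lost its call without hydrogel eye 2 (0.0705) [7.47e-07 to 0.290]. Aqp1 lost its call without PBS eye 1 (0.0634) and PBS eye 2 (0.0648) [1.24e-04 to 0.0977]. Slc4a11 [2.40e-07 to 0.438], Aldh1a1 [4.27e-07 to 0.156], Slc22a6 [1.87e-05 to 0.0559], Pdgfra [9.62e-06 to 0.966] and Wfdc1 [1.24e-04 to 0.598] lost calls in other settings.

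Stress and growth lists moved less evenly. Of the reactive gliosis list, in which the protease inhibitor Timp1 rose by 3.4 ± 0.22 and complement C3 by 3.53 ± 0.32, 9 of 20 rose, 2 fell and 9 did not pass (list alone: 13 higher and 2 lower), with the metallothionein Mt2A (2.65 ± 0.21); median 0.94 (camera adjusted p = 0.00359, estimated 0.593). The astrocyte filament Gfap was 1 of its falling members (-0.57 ± 0.15), but not in the sum of the 7 regions (0.29). Of the ribosomal protein list, with Rpl4 at 1.1 ± 0.17, 22 of 28 rose and 6 did not pass (list alone: 25 higher); median 0.74 (camera adjusted p = 3.41e-08, estimated 0.593). Of the immediate early list, with Myc at 2.17 ± 0.22, 6 of 17 rose and 11 did not pass (list alone: 8 higher), with the growth inhibitor Btg2 (0.97 ± 0.17); median 0.66 (camera adjusted p = 0.00268, estimated 0.619). Of the apoptosis and p53 list, with the death agonist Bid at 2.85 ± 0.3, 8 of 14 rose and 6 did not pass (list alone: 9 higher), with the death agonist Pmaip1 (2.59 ± 0.3); median 0.98 (camera adjusted p = 2.22e-04, estimated 0.593). Of the cholesterol synthesis list, 1 of 18 rose, 2 fell and 15 did not pass (list alone: 1 higher and 7 lower), with the sterol carrier Stard4 (2.13 ± 0.38) and the sterol sensor partner Insig1 (-0.82 ± 0.15); median -0.33 (camera adjusted p = 0.0324, estimated 0.619). The unfolded protein list had 8 members higher of 20, among them the folate enzyme Mthfd2 (2.4 ± 0.31), and the oxidative stress list 6 of 20, among them Gpx1, which reduces peroxides (2.13 ± 0.26). The matrix remodelling list had 8 higher and 1 lower of 26, with Timp1 and the adhesion protein Tgfbi (1.89 ± 0.24) among the higher ones. Camera called 25 of 48 lists in whole sections, 13 higher and 12 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.593; 1 at an unadjusted p below 0.05), and fry called 1. The glaucoma gene list had 4 higher of 20, the RGC injury list 1 higher and 2 lower of 17, and the hypoxia list 1 higher and 3 lower of 22. Of the mitochondrial genome list of oxidative phosphorylation, edgeR called 0 of 13, DESeq2 called 1, and 4 had an unadjusted p below 0.05. Of the nuclear genome list of oxidative phosphorylation, edgeR called 0 of 33, DESeq2 called 0, and 6 had an unadjusted p below 0.05. Gfap lost its call without hydrogel eye 2 (0.136), PBS eye 1 (0.220), PBS eye 2 (0.0737), hydrogel eye 1 section 1 (0.190), hydrogel eye 2 section 1 (0.0513), hydrogel eye 2 section 2 (0.0750) and PBS eye 2 section 1 (0.321) [0.0125 to 0.597]. Insig1 lost its call without hydrogel eye 2 (0.0583), PBS eye 2 (0.0545) and hydrogel eye 1 section 2 (0.0537) [0.00108 to 0.634]. Rpl4 [1.08e-06 to 0.104], Myc [9.10e-12 to 0.154], Btg2 [2.85e-04 to 0.707], Bid [1.76e-13 to 0.156], Pmaip1 [1.01e-10 to 0.537], Stard4 [3.90e-05 to 0.644], Mthfd2 [5.10e-11 to 0.257], Gpx1 [2.35e-14 to 0.0655] and Tgfbi [1.13e-11 to 0.978] lost calls in other settings.

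Sections differ in how much of each tissue they hold, so the 7 regions were also summed without the other spots, at their own shares (added after the data were seen) and at equal shares in every eye. 341 genes were called at their own and 648 at equal shares, so the fall from 2772 went with leaving out the other spots, not with equal shares. Of the ganglion cell genes, 0 of 15 were called by edgeR at their own shares (3 at an unadjusted p below 0.05, median -0.32, camera adjusted p = 0.00133, estimated 0.693) and 9 of 15 fell at equal shares (median -0.73, camera adjusted p = 2.66e-09, estimated 0.505). Of the myelin genes, 1 of 14 fell at their own shares (median -1.08, camera adjusted p = 2.41e-05, estimated 0.693) and none at equal shares (0 of 14 by edgeR, 2 at an unadjusted p below 0.05, median -0.25, camera adjusted p = 0.407). Gfap changed from -0.57 in whole sections to 0.29 at their own (adjusted p = 0.520) and 0.72 at equal shares (adjusted p = 0.0223), and the glial calcium sensor S100b from -0.99 to -0.14 (adjusted p = 0.854) and 0.51 (adjusted p = 0.114). Numbers of genes called higher at their own and equal shares were macrophage (13 and 14 of 16), lymphocyte (5 and 6 of 6), MHC class II (6 and 6 of 7), MHC class I (9 and 11 of 12), complement (9 and 9 of 13), cytokine (9 of 18 and 10 of 17), reactive gliosis (6 and 12 of 20), interferon (5 and 10 of 19) and cell cycle (2 and 7 of 16). Of the lens list 9 and 12 of 14 were called lower. Among the lists with few calls at equal shares (median there, in whole sections; camera adjusted p there) were 2 of 26 ribosomal protein (0.23, 0.74; 5.59e-04), 2 of 11 amacrine (-0.38, -0.98; 8.86e-05), 2 of 22 synapse (-0.44, -0.9; 1.89e-04), 1 of 13 apoptosis (0.46, 0.98; 0.00865) and 1 of 15 immediate early (0.29, 0.66; 0.0401) genes. Camera called these in the same direction at equal shares (none with an estimated correlation, adjusted p = 0.494 to 0.567), but at their own shares not synapse (adjusted p = 0.120) and immediate early genes (0.225). S100b lost its call without hydrogel eye 1 (0.0561), hydrogel eye 2 (0.162), PBS eye 1 (0.190), hydrogel eye 1 section 1 (0.0713), hydrogel eye 2 section 1 (0.0535), hydrogel eye 2 section 2 (0.0562) and PBS eye 2 section 1 (0.178) [0.00283 to 0.854].

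**Figure D2:**
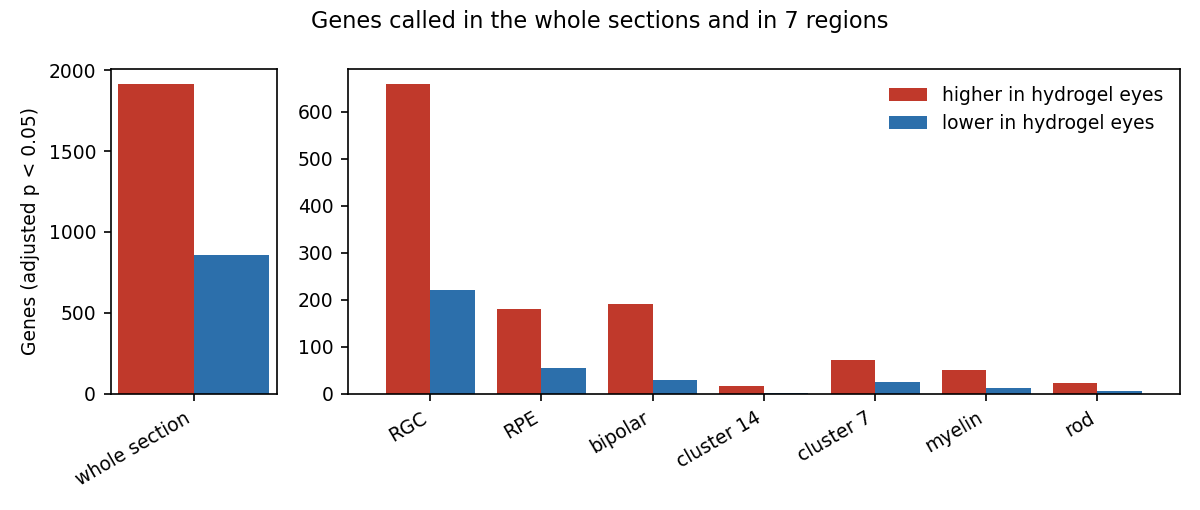
Number of genes with an adjusted p below 0.05 in the whole sections (left axis) and in each of the 7 regions (right axis, own scale), split by direction, from 2 hydrogel and 2 PBS eyes. More genes were higher than lower in each comparison, for example 658 against 221 in the RGC region.

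Within the RGC region, glial and immune genes rose in hydrogel eyes. The astrocyte and Müller cell filament Gfap rose by 2.35 ± 0.24 (734 ± 393 against 154 ± 29.4 CPM, adjusted p = 5.10e-07). The complement subunit C1qc rose by 3.34 ± 0.21 and the lysozyme Lyz2 of macrophages by 4.79 ± 0.3. The MHC class II genes RT1-Da and RT1-Ba, which present peptides to T cells, rose too (5.47 ± 0.23 and 5.52 ± 0.31). The scavenger receptor Cd163 and the lectin Fcnb had no PBS counts and were at least 46.8-fold and at least 30.2-fold higher. Several named genes had 1 or 2 PBS counts: RT1-Bb (ratio 469.6, 95% CI 129.6 to 3883), Ubd (466, 95% CI 83.3 to 18450), Cxcl10 (229, 95% CI 40.7 to 9089.9), Cxcl11 (84.8, 95% CI 23.1 to 706), Cxcl9 (72.2, 95% CI 19.6 to 601), RT1-DOa (68.8, 95% CI 18.7 to 573), the adaptor Fyb1 (44.9, 95% CI 12.1 to 376) and AABR07017902.1 (87.8, 95% CI 15.4 to 3505). In all 879 of 9197 genes tested were called, 658 higher and 221 lower, of which 33 define the region and are not described. DESeq2 called 334, and with free RNA taken off edgeR called 399 (corneal rate) and 276 (Ubd-led cluster). Without the first section of hydrogel eye 2 the count was 436, and without the second section of PBS eye 2 it was 463.

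Of the macrophage list in the RGC region, with C1qc and Laptm5 (3.78 ± 0.25), all 16 rose (list alone: 16 higher); median 2.85 (camera adjusted p = 1.34e-19, estimated 0.381). Of the reactive gliosis list, with the metallothioneins Mt2A (3.01 ± 0.19) and Mt1 (2.04 ± 0.17), 16 of 18 rose and 2 did not pass (list alone: 17 higher), with Timp1 (3.29 ± 0.27); median 1.92 (camera adjusted p = 4.21e-13, estimated 0.381). Of the complement list, with Serping1 at 2.75 ± 0.16, 10 of 11 rose and 1 did not pass (list alone: 10 higher); median 2.75 (camera adjusted p = 4.45e-11, estimated 0.381). Of the MHC class II list all 7 rose (list alone: 7 higher); median 5.47 (camera adjusted p = 8.26e-12, estimated 0.381). Of the MHC class I list, with B2m at 2.49 ± 0.18, all 11 rose (list alone: 11 higher), with RT1-A1 (3.94 ± 0.18); median 2.16 (camera adjusted p = 2.68e-12, estimated 0.396). Of the interferon list, with Gbp2 at 4.02 ± 0.25 and the antiviral Ifitm3 at 1.52 ± 0.16, 13 of 19 rose and 6 did not pass (list alone: 15 higher); median 1.51 (camera adjusted p = 4.21e-13, estimated 0.381). Of the Müller glia list, with the glutamate carrier Slc1a3 (1.08 ± 0.14), the chaperone Clu (1.02 ± 0.15) and the lipid carrier Apoe (1.06 ± 0.18), 5 of 10 rose and 5 did not pass (list alone: 6 higher); median 0.63 (camera adjusted p = 0.00354, estimated 0.499). Of the matrix list, with fibronectin Fn1 at 1.23 ± 0.18 and Sparc at 0.93 ± 0.15, 11 of 19 rose and 8 did not pass (list alone: 15 higher); median 0.86 (camera adjusted p = 1.74e-08, estimated 0.381). Of the fibroblast list, with the proteoglycan Bgn at 1.46 ± 0.16, 9 of 13 rose and 4 did not pass (list alone: 9 higher), with the calcification inhibitor Mgp (0.97 ± 0.15); median 0.97 (camera adjusted p = 1.74e-05, estimated 0.396). Apoe lost its call without hydrogel eye 2 section 1 (0.0540) [7.40e-18 to 0.0542]. Timp1 [2.41e-28 to 0.139], Fn1 [7.01e-09 to 0.0892] and Sparc [1.05e-10 to 0.0586] lost calls in other settings.

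A minority of the synaptic and cholesterol genes changed in the RGC region, most of these downward. The vesicle protein Vamp2 had a log2 fold change of -0.58 ± 0.14 and the complexin Cplx2 of -0.89 ± 0.23. Of the synapse list 1 of 19 rose, 6 fell and 12 did not pass (list alone: 1 higher and 8 lower), with the complexin Cplx4 (1.67 ± 0.43); median -0.34 (camera adjusted p = 0.00529, estimated 0.381). Fdft1, which makes squalene, stood at -0.61 ± 0.15. Of the cholesterol synthesis list 3 of 17 fell and 14 did not pass (list alone: 6 lower), with Insig1 (-0.66 ± 0.16); median -0.35 (camera adjusted p = 1.71e-04, estimated 0.396). Of the ganglion cell list without the genes that define the region, edgeR called 0 of 4, DESeq2 called 0, and 3 had an unadjusted p below 0.05. Their median was -0.61 (camera adjusted p = 0.0392, estimated 0.566). Of the bipolar list, with the homeobox gene Isl1 at -0.76 ± 0.18, 1 of 9 fell and 8 did not pass (list alone: 1 lower); median 0.19 (camera adjusted p = 0.671, estimated 0.843). Crystallins and epithelial genes were lower as well. The crystallins were Crygd (-3.89 ± 0.44), Crygb (-3.29 ± 0.49), Crygs (-3.2 ± 0.53), Cryaa (-2.63 ± 0.38), Cryga (-2.08 ± 0.32) and Crybb2 (-2.18 ± 0.5). The epithelial genes were Slurp1 (-2.72 ± 0.28), Krt75 (-2.08 ± 0.4) and S100g (-3.49 ± 0.42). Of the lens list 10 of 12 fell and 2 did not pass (list alone: 12 lower); median -2.4 (camera adjusted p = 8.08e-11, estimated 0.415). Of the surface epithelium list 5 of 11 fell and 6 did not pass (list alone: 7 lower), with the water channel Aqp5 (-1.32 ± 0.22) and the corneal dehydrogenase Aldh3a1 (-1.48 ± 0.3); median -0.65 (camera adjusted p = 1.98e-04, estimated 0.499). Crygc had 3 and Hba-a3 had 1 hydrogel counts (ratios 0.0308, 95% CI 0.00624 to 0.0928 and 0.0112, 95% CI 2.81e-04 to 0.0641), and the haemoglobin gene LOC100134871 stood at -1.53 ± 0.36. Vamp2 lost its call without PBS eye 1 (0.142) and PBS eye 2 section 2 (0.117) [8.93e-04 to 0.302]. Cplx2 lost its call without hydrogel eye 1 (0.0501), hydrogel eye 2 (0.0562), PBS eye 1 (0.0629), hydrogel eye 1 section 1 (0.0684), hydrogel eye 2 section 2 (0.0690), PBS eye 1 section 1 (0.0770) and PBS eye 2 section 2 (0.102) [0.00959 to 0.327]. Cplx4 lost its call without hydrogel eye 2 (0.0958), PBS eye 1 (0.242), hydrogel eye 2 section 1 (0.141), PBS eye 1 section 1 (0.0558), PBS eye 1 section 2 (0.0552) and PBS eye 2 section 2 (0.0797) [0.00101 to 0.302]. Fdft1 lost its call without hydrogel eye 2 section 1 (0.0932) and PBS eye 2 section 2 (0.0550) [0.00316 to 0.136]. Insig1 lost its call without hydrogel eye 2 (0.0992), PBS eye 1 (0.0737), hydrogel eye 1 section 2 (0.0763), hydrogel eye 2 section 1 (0.0530) and PBS eye 2 section 2 (0.127) [0.00291 to 0.509]. Isl1 lost its call without hydrogel eye 2 (0.0984) and hydrogel eye 2 section 1 (0.143) [0.00344 to 0.364]. Crybb2 lost its call without hydrogel eye 1 section 2 (0.0513) and hydrogel eye 2 section 1 (0.109) [1.00e-15 to 0.895]. LOC100134871 lost its call without PBS eye 2 (0.324), hydrogel eye 2 section 1 (0.116), hydrogel eye 2 section 2 (0.0513) and PBS eye 2 section 1 (0.0856) [2.92e-17 to 0.584]. Crygb [5.30e-17 to 0.0824], Crygs [3.46e-13 to 0.0665], Cryaa [3.99e-15 to 0.140], Cryga [1.32e-11 to 0.139], Krt75 [2.47e-11 to 0.221], Aqp5 [4.14e-12 to 0.244] and Aldh3a1 [4.48e-46 to 0.484] lost calls in other settings.

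**Figure D3:**
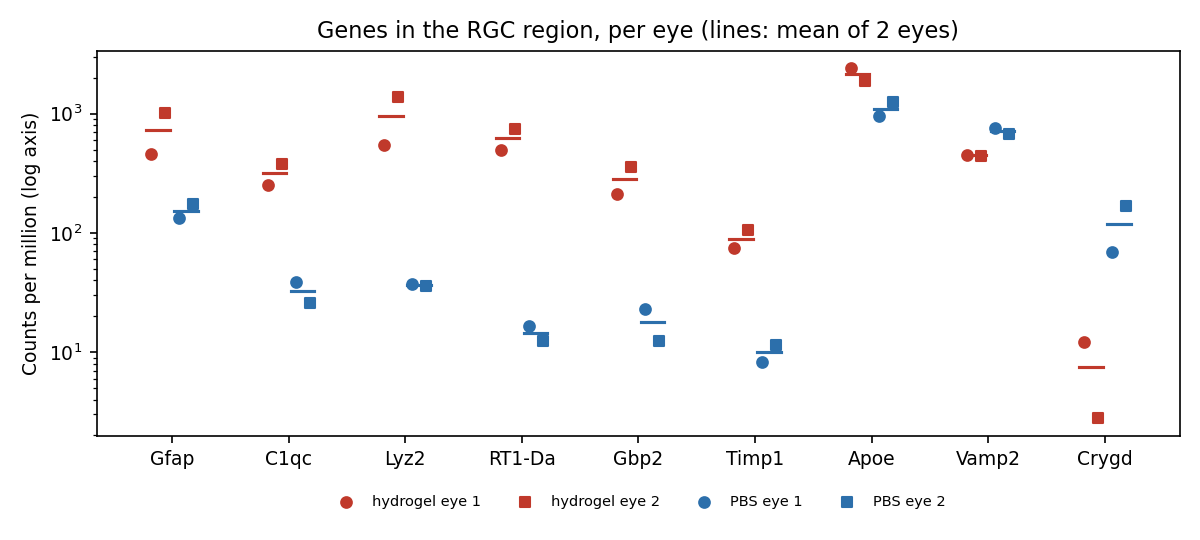
CPM of 9 genes in the RGC region on a log axis, with 1 point per eye (red: hydrogel, blue: PBS, n = 2 eyes per group) and a line at each group's mean. Gfap lay at 734 CPM in hydrogel and 154 CPM in PBS eyes, and both hydrogel eyes lay above both PBS eyes.

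In the RPE region, complement genes and some matrix genes rose beside immune genes. Complement C3 rose by 3.65 ± 0.32 (269 ± 34.1 against 21.7 ± 11.1 CPM, adjusted p = 2.04e-09) and the mitochondrial superoxide dismutase Sod2 by 1.76 ± 0.23. The collagen-binding Fmod rose by 2.01 ± 0.25 and the collagen Col12a1 by 1.78 ± 0.25. Cxcl9 rose by 5.05 ± 0.45, while Ubd, Cxcl11 and Cd8a had no PBS counts and were at least 102-fold, at least 35.4-fold and at least 14.3-fold higher. Fcnb had 1 PBS count (ratio 30.5, 95% CI 5.02 to 1248). The serpin Serpine3 had no hydrogel counts and was at least 18.0-fold lower, and Hba-a3 was at least 12.1-fold lower. Of the complement list 7 of 10 rose and 3 did not pass (list alone: 8 higher), with Serping1 (1.23 ± 0.19); median 1.09 (camera adjusted p = 1.05e-08, estimated 0.324). Of the macrophage list 11 of 14 rose and 3 did not pass (list alone: 13 higher), with Lyz2 (2.18 ± 0.19) and Laptm5 (2.3 ± 0.26); median 1.25 (camera adjusted p = 9.44e-13, estimated 0.324). Of the fibroblast list 5 of 13 rose and 8 did not pass (list alone: 6 higher and 1 lower); median 0.31 (camera adjusted p = 0.00744, estimated 0.637). The lens genes Crygd (-4.36 ± 0.5), Crygc (ratio 0.0240, 95% CI 5.96e-04 to 0.141) and Crygb (ratio 0.0364, 95% CI 0.00431 to 0.137) fell. Of the lens list all 6 fell (list alone: 6 lower); median -3.55 (camera adjusted p = 3.40e-12, estimated 0.334). In all 234 of 6150 genes tested were called, 180 higher and 54 lower. DESeq2 called 74, and with free RNA taken off at these rates edgeR called 30 and 93. Sod2 [8.42e-10 to 0.331], Col12a1 [4.63e-10 to 0.111], Fcnb [3.53e-06 to 0.399], Serpine3 [8.83e-17 to 0.0570], Hba-a3 [2.22e-09 to 0.0796] and Serping1 [1.46e-08 to 0.375] lost calls in other settings.

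In the bipolar region, Lyz2 rose by 4.64 ± 0.29, RT1-Da by 5.0 ± 0.25, C1qb by 2.67 ± 0.27 and Gbp2 by 3.94 ± 0.33. Cxcl11, AABR07017902.1 and the membrane protein Ms4a6a had no PBS counts and were at least 39.2-fold, at least 30.6-fold and at least 14.7-fold higher, and Ubd (ratio 357, 95% CI 63.6 to 14148) and RT1-Bb (ratio 333, 95% CI 91.7 to 2753) had 1 and 2. The serine protease Prss56 had no hydrogel counts and was at least 26.4-fold lower, and Crygb was at least 19.8-fold lower. Crygd (-3.31 ± 0.45), S100g (-3.21 ± 0.44) and Slurp1 (-2.71 ± 0.38) fell. Of the macrophage list 14 of 15 rose and 1 did not pass (list alone: 14 higher); median 2.38 (camera adjusted p = 1.99e-24, estimated 0.306). Of the Müller glia list 2 of 7 rose and 5 did not pass (list alone: 3 higher), with Clu (0.73 ± 0.15) and Apoe (0.72 ± 0.16) called; median 0.48 (camera adjusted p = 0.0860, estimated 0.453). Of the myelin list 5 of 7 fell and 2 did not pass (list alone: 6 lower), with Mbp (-1.56 ± 0.23); median -1.64 (camera adjusted p = 1.33e-08, estimated 0.310). With free RNA at the corneal rate taken off (chosen after the data were seen), Mbp turned to 7.24 log2 (adjusted p = 0.0393). Over-subtraction could give this. In all 221 of 8110 genes tested were called, 191 higher and 30 lower, and without the first section of hydrogel eye 1 the count was 126. DESeq2 called 117, and with free RNA taken off at these rates edgeR called 25 and 40. Clu lost its call without PBS eye 1 (0.104), hydrogel eye 1 section 1 (0.0793) and PBS eye 2 section 2 (0.0658) [1.19e-04 to 0.119]. Apoe lost its call without hydrogel eye 1 (0.119), PBS eye 2 (0.0706), hydrogel eye 1 section 1 (0.0974), hydrogel eye 2 section 2 (0.0525), PBS eye 1 section 1 (0.108) and PBS eye 2 section 2 (0.0939) [1.83e-07 to 0.483]. C1qb [1.07e-22 to 0.0608], Gbp2 [6.50e-51 to 0.218], Slurp1 [1.32e-37 to 0.679] and Mbp [4.60e-17 to 0.173] lost calls in other settings.

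In cluster 14, led by neurofilament and astrocyte genes, genes of antigen presentation rose. Cd74, the invariant chain of MHC class II, rose by 4.3 ± 0.41 (1666 ± 35.2 against 87.2 ± 38.9 CPM), RT1-Da by 4.85 ± 0.45 and RT1-Db1 by 4.21 ± 0.47, while RT1-Bb and Ubd had no PBS counts and were at least 49.7-fold and at least 22.3-fold higher. Crygd had 1 hydrogel count (ratio 0.0329, 95% CI 8.20e-04 to 0.191). Of the MHC class II list all 5 rose (list alone: 5 higher); median 4.3 (camera adjusted p = 7.48e-14, estimated 0.292). Of the macrophage list 3 of 10 rose and 7 did not pass (list alone: 10 higher), with Lyz2 (2.81 ± 0.36) and Tyrobp (2.61 ± 0.43); median 1.83 (camera adjusted p = 2.95e-13, estimated 0.292). In all 17 of 2872 genes tested were called, 16 higher and 1 lower, with 77 without hydrogel eye 2, 27 without PBS eye 1, 30 without PBS eye 2 and 5 without the second section of PBS eye 2. DESeq2 called 14, and with free RNA taken off at these rates edgeR called 0 and 2. Ubd lost its call without PBS eye 2 section 2 (0.123) [1.03e-11 to 0.595]. Crygd lost its call without hydrogel eye 1 (0.0954), PBS eye 2 (0.103), hydrogel eye 1 section 2 (0.0556) and PBS eye 2 section 2 (0.113) [6.34e-06 to 0.679]. Tyrobp lost its call without hydrogel eye 1 (0.103), PBS eye 2 (0.0856), PBS eye 1 section 2 (0.0980) and PBS eye 2 section 2 (0.115) [7.34e-10 to 0.679]. Cd74 [4.69e-39 to 0.679], RT1-Db1 [2.79e-18 to 0.121], RT1-Bb [1.46e-23 to 0.156] and Lyz2 [2.77e-15 to 0.850] lost calls in other settings.

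In cluster 7, led by Igfbp6 and haemoglobin genes, the monocyte attractant Ccl2 rose by 4.49 ± 0.49, Cxcl10 by 4.01 ± 0.48, RT1-Bb by 5.6 ± 0.36 and RT1-Da by 2.7 ± 0.27. Ubd (ratio 361, 95% CI 64.3 to 14333), Cxcl11 (132, 95% CI 23.2 to 5283), RT1-T24-4 (32.7, 95% CI 10.7 to 163) and the T-cell checkpoint receptor Lag3 (26.3, 95% CI 6.79 to 225) had 1 to 3 PBS counts. Crygd (-4.77 ± 0.5) and Cryga (-3.49 ± 0.59) fell, and Crygb (0.0248, 95% CI 0.00296 to 0.0915), S100g (0.0431, 95% CI 0.00512 to 0.162) and Cryba1 (0.0678, 95% CI 0.00795 to 0.261) had 2 hydrogel counts each. Of the cytokine list 3 of 11 rose and 8 did not pass (list alone: 7 higher); median 1.02 (camera adjusted p = 1.01e-05, estimated 0.405). Of the lens list all 8 fell (list alone: 8 lower); median -3.45 (camera adjusted p = 8.22e-13, estimated 0.405). In all 95 of 6513 genes tested were called, 71 higher and 24 lower. Leaving out 1 section gave 61 (first of hydrogel eye 1), 56 (first of hydrogel eye 2), 61 and 59 (PBS eye 1) and 38 (first of PBS eye 2). DESeq2 called 56, and with free RNA taken off at these rates edgeR called 6 and 18. Lag3 lost its call without hydrogel eye 1 (0.116) [2.86e-09 to 0.116]. Cryga lost its call without PBS eye 1 section 1 (0.0528) and PBS eye 2 section 1 (0.155) [1.61e-09 to 0.306]. S100g lost its call without hydrogel eye 1 (0.0557), PBS eye 1 (0.198), hydrogel eye 1 section 1 (0.0575), hydrogel eye 2 section 1 (0.0792), PBS eye 1 section 1 (0.0528), PBS eye 1 section 2 (0.0641) and PBS eye 2 section 1 (0.133) [4.33e-09 to 0.198]. Cryba1 lost its call without hydrogel eye 2 (0.0968), PBS eye 1 (0.309), PBS eye 2 (0.107), hydrogel eye 1 section 1 (0.0867), hydrogel eye 2 section 1 (0.0659), PBS eye 1 section 1 (0.0837) and PBS eye 1 section 2 (0.0594) [2.44e-05 to 0.503]. Cxcl10 [3.37e-19 to 0.0896], RT1-Da [6.42e-25 to 0.955], Cxcl11 [1.88e-26 to 0.0896], RT1-T24-4 [5.12e-17 to 0.2] and Crygb [1.43e-16 to 0.0596] lost calls in other settings.

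In the myelin region, some genes of cholesterol synthesis fell and some glial and immune genes rose. Hmgcs1, which commits acetyl-CoA to the pathway, stood at -1.19 ± 0.2 (292 ± 95 against 681 ± 20.0 CPM) and Fdps, which makes farnesyl diphosphate, at -1.07 ± 0.19. Of the cholesterol synthesis list 4 of 16 fell and 12 did not pass (list alone: 12 lower); median -0.82 (camera adjusted p = 3.76e-09, estimated 0.350). Clu rose by 0.95 ± 0.15, Mt1 by 1.59 ± 0.21, Lyz2 by 2.42 ± 0.23, Gbp2 by 2.65 ± 0.24 and the protease inhibitor Slpi by 3.96 ± 0.39. With free RNA of the Ubd-led cluster taken off, the log2 fold change of Lyz2 was -0.194. RT1-T24-4 rose by 3.88 ± 0.56. RT1-Bb (ratio 163, 95% CI 44.2 to 1355), Ubd (185, 95% CI 32.4 to 7401) and Cxcl11 (29.1, 95% CI 7.31 to 252) had 1 or 2 PBS counts. Cryaa had no hydrogel counts and was at least 8.67-fold lower, Slurp1 stood at -2.4 ± 0.49, and Crygd (0.0242, 95% CI 6.06e-04 to 0.138), Crygb (0.0440, 95% CI 0.00109 to 0.257) and S100g (0.0440, 95% CI 0.00109 to 0.257) had 1 hydrogel count each. Of the reactive gliosis list 4 of 15 rose and 11 did not pass (list alone: 9 higher), with Timp1 (1.79 ± 0.25); median 0.65 (camera adjusted p = 3.23e-07, estimated 0.350). In all 63 of 4286 genes tested were called, 50 higher and 13 lower, with 118 without hydrogel eye 2, 134 without PBS eye 2 and 116 without the second section of PBS eye 2. DESeq2 called 28, and with free RNA taken off at these rates edgeR called 16 and 21. RT1-T24-4 lost its call without hydrogel eye 1 (0.104) and hydrogel eye 2 (0.411) [1.86e-07 to 0.411]. Cxcl11 lost its call without hydrogel eye 1 (0.132) and PBS eye 2 (0.0866) [2.64e-08 to 0.132]. Crygd lost its call without hydrogel eye 1 section 1 (0.0509) [3.97e-18 to 0.0673]. Crygb lost its call without hydrogel eye 2 (0.0529), PBS eye 1 (0.121) and PBS eye 2 (0.297) [3.71e-05 to 0.297]. S100g lost its call without hydrogel eye 1 (0.0697) and PBS eye 2 (0.105) [5.12e-05 to 0.356]. Fdps [2.30e-04 to 0.357], Lyz2 [1.02e-24 to 0.965], Gbp2 [1.58e-20 to 0.0848], RT1-Bb [2.54e-49 to 0.0808], Cryaa [2.11e-07 to 0.0858], Slurp1 [7.32e-11 to 0.592] and Timp1 [2.75e-07 to 0.109] lost calls in other settings.

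In the rod region, where UMIs were fewest, at 47395 to 210340 per eye, Lyz2 rose by 3.95 ± 0.5, RT1-Da by 4.33 ± 0.48 and B2m by 2.51 ± 0.32. RT1-Bb and Laptm5 had no PBS counts and were at least 31.5-fold and at least 8.50-fold higher, and Ubd (ratio 54.0, 95% CI 9.39 to 2162), RT1-Ba (24.0, 95% CI 7.97 to 118) and the lectin Clec10a (25.5, 95% CI 4.28 to 1036) had 1 to 3. Rpe65 of the RPE (-3.0 ± 0.5), corneal Aldh3a1 (-1.65 ± 0.31), Slurp1 (-2.52 ± 0.48) and Lypd2 (-1.63 ± 0.35) fell. Crygd had 1 hydrogel count (ratio 0.0167, 95% CI 4.13e-04 to 0.0977). Of the complement list 2 of 6 rose and 4 did not pass (list alone: 6 higher), with Serping1 (2.69 ± 0.38) and C1qa (3.03 ± 0.67) called; median 2.1 (camera adjusted p = 1.60e-10, estimated 0.587). In all 28 of 2268 genes tested were called, 23 higher and 5 lower, with 8 without hydrogel eye 1, 13 without hydrogel eye 2, 17 without PBS eye 2, and 16, 10 and 17 without the first section of hydrogel eye 1, the second of hydrogel eye 2 and the first of PBS eye 1. DESeq2 called 16, and with free RNA taken off at these rates edgeR called 0 and 14. RT1-Da lost its call without hydrogel eye 1 (0.0713) [3.55e-15 to 0.121]. Laptm5 lost its call without hydrogel eye 2 (0.610), PBS eye 2 (0.122) and hydrogel eye 2 section 2 (0.123) [1.27e-05 to 0.615]. Ubd lost its call without hydrogel eye 2 (0.100), hydrogel eye 1 section 1 (0.0713) and hydrogel eye 2 section 2 (0.152) [2.39e-11 to 0.152]. RT1-Ba lost its call without hydrogel eye 1 (0.0519) [8.97e-11 to 0.121]. Clec10a lost its call without hydrogel eye 2 (0.520), PBS eye 2 (0.494), hydrogel eye 1 section 1 (0.119) and hydrogel eye 2 section 2 (0.142) [3.36e-04 to 0.576]. Rpe65 lost its call without hydrogel eye 1 (0.483), hydrogel eye 2 (0.248), PBS eye 2 (0.122) and hydrogel eye 2 section 2 (0.131) [1.80e-08 to 0.824]. Aldh3a1 lost its call without hydrogel eye 1 (0.0519), hydrogel eye 2 (0.0981), PBS eye 2 (0.178), hydrogel eye 1 section 1 (0.0608) and hydrogel eye 2 section 2 (0.142) [2.81e-05 to 0.9999]. Slurp1 lost its call without hydrogel eye 1 (0.468), hydrogel eye 2 (0.284), PBS eye 2 (0.376), hydrogel eye 1 section 1 (0.0675), hydrogel eye 1 section 2 (0.0505) and hydrogel eye 2 section 2 (0.142) [3.31e-05 to 0.468]. Lypd2 lost its call without hydrogel eye 1 (0.199), hydrogel eye 2 (0.239), PBS eye 2 (0.226), hydrogel eye 1 section 2 (0.212) and hydrogel eye 2 section 2 (0.182) [7.18e-04 to 0.639]. Crygd lost its call without hydrogel eye 1 (0.250) and PBS eye 2 (0.376) [9.32e-09 to 0.824]. C1qa lost its call without hydrogel eye 1 (0.0632), hydrogel eye 2 (0.240), hydrogel eye 1 section 1 (0.197), hydrogel eye 2 section 2 (0.364) and PBS eye 1 section 1 (0.0570) [5.65e-05 to 0.364]. Lyz2 [5.73e-17 to 0.121], B2m [2.09e-11 to 0.121], RT1-Bb [2.53e-18 to 0.121] and Serping1 [2.68e-07 to 0.9999] lost calls in other settings.

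**Figure D4:**
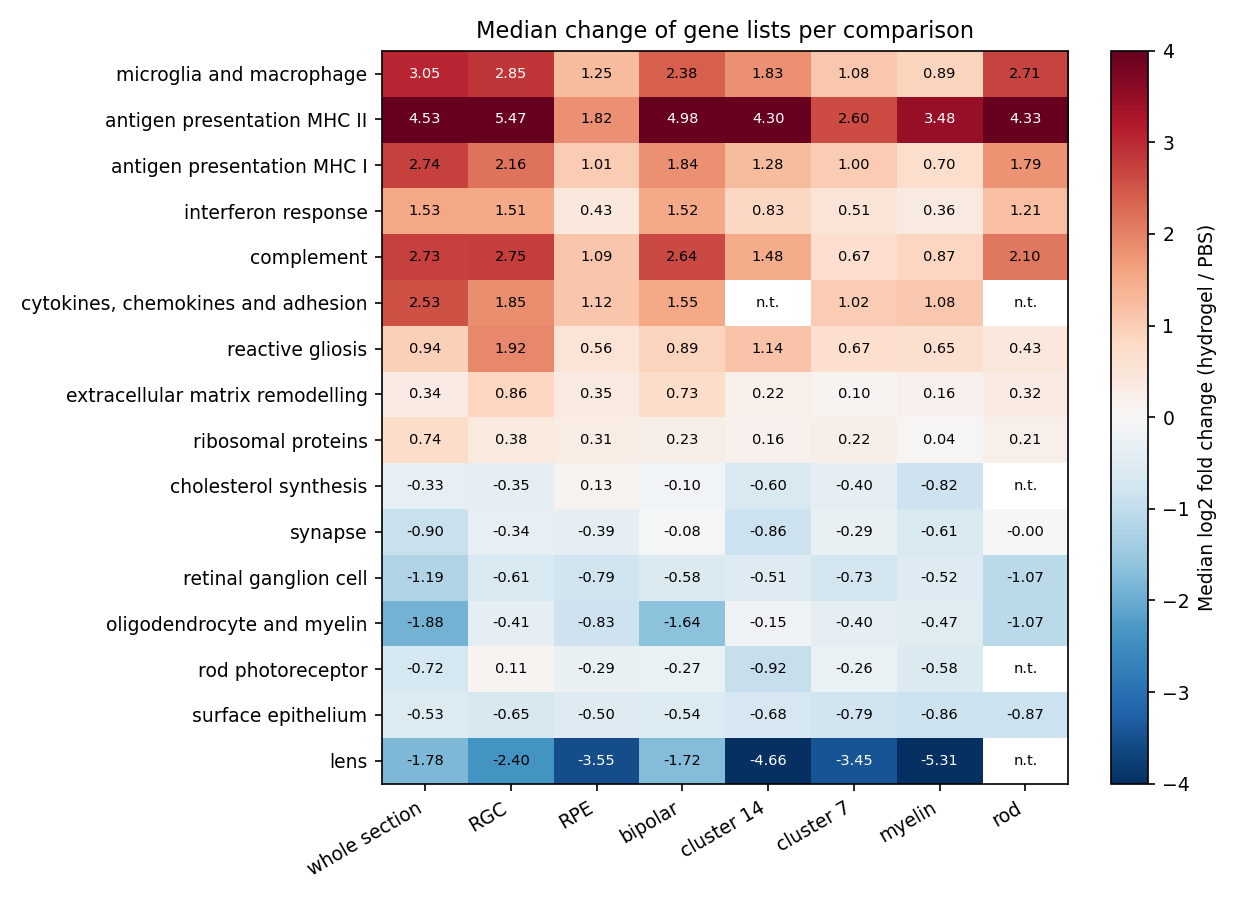
Median log2 fold change (hydrogel over PBS, n = 2 eyes per group) of the tested members of 16 gene lists in the whole sections and the 7 regions, with n.t. where fewer than 3 members were tested. The MHC class II list had a median of 1.82 in the RPE region and 5.47 in the RGC region.

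Across regions, 699 genes were called higher and 266 lower in 1 or more of the 7. The genes called higher in all 7 were Cd74, Coro1a, Gbp2, Ifi30, Lyz2, RT1-A1, RT1-Ba, RT1-Bb, RT1-Da, RT1-Db1, Timp1 and Ubd, and Crygd was called lower in all 7. RNA of the cornea was detected in every region: the summed level of Krt12 and Aldh3a1, corneal epithelial genes, was 13.3 to 14.9% of its whole-eye level in the RGC region, 14.3 to 16.1% in the myelin region, 23.6 to 27.2% in the bipolar region, 25.2 to 32.4% in the RPE region and 28.8 to 42.1% in the rod region. The removal of free RNA was chosen after the data were seen. When the profile of the Ubd-led cluster was subtracted at the rate of its 10 leading genes, 227 of the 658 genes called higher in the RGC region were still called, of 539 still tested, and their median log2 fold change went from 1.6 to 1.03. In cluster 7 it was 7 of 71 (50 tested, 2.2 to 1.16) and in the rod region 10 of 23 (13 tested, 3.64 to 2.46), the lowest and highest shares of the 7.

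The RGC region was compared with each other region of the same eyes by an interaction term. Gfap, Cd74 and Lyz2 were picked after values were seen. The log2 fold change of Gfap was higher in the RGC region than in the RPE (2.79 ± 0.29, adjusted p = 1.24e-09), bipolar (2.49 ± 0.23, adjusted p = 1.03e-08), rod (2.69 ± 0.39, adjusted p = 9.04e-08) and myelin (1.64 ± 0.27, adjusted p = 5.06e-04) regions, cluster 7 (1.55 ± 0.32, adjusted p = 0.00353) and cluster 14 (2.0 ± 0.39, adjusted p = 9.41e-04). In the RPE, bipolar and rod regions it was itself -0.62, -0.28 and -0.64 (adjusted p = 0.241, 0.882 and 0.878), not a rise. Cd74 rose more in the RGC region than in the RPE region (2.92 ± 0.22, adjusted p = 8.15e-14), the myelin region (1.85 ± 0.26, adjusted p = 4.58e-05) and cluster 7 (2.35 ± 0.25, adjusted p = 5.10e-08). Its differences from the bipolar region (-0.00422 ± 0.17, adjusted p = 0.997), cluster 14 (0.29 ± 0.42, adjusted p = 0.967) and the rod region (0.68 ± 0.38, adjusted p = 1) did not pass. Lyz2 rose more than in the RPE region (2.44 ± 0.27, adjusted p = 8.58e-09), the myelin region (2.22 ± 0.29, adjusted p = 1.70e-05), cluster 7 (3.01 ± 0.29, adjusted p = 8.71e-09) and cluster 14 (1.91 ± 0.41, adjusted p = 0.00445), and its differences from the bipolar region (-0.0114 ± 0.24, adjusted p = 0.996) and the rod region (0.63 ± 0.47, adjusted p = 1) did not pass. Against the RPE and bipolar regions, clusters 14 and 7 and the myelin and rod regions, 136, 29, 39, 107, 108 and 3 genes differed. Of these, 129, 24, 37, 100, 88 and 3 changed more upward in the RGC region. Its clusters 4 and 16, mostly split by treatment, could add to this. Against the RPE region it was 86 without hydrogel eye 2 and 54 without PBS eye 1. Against the bipolar region it was 50 without hydrogel eye 1 and 60 without PBS eye 2. Against cluster 14 it was 15 without hydrogel eye 2, 1 without PBS eye 1 and 6 without PBS eye 2. Against the myelin region it was 51 without hydrogel eye 2 and 57 without PBS eye 1. Against the rod region it was 11 without hydrogel eye 1, 10 without hydrogel eye 2, 1 without PBS eye 1 and 1 without PBS eye 2. The difference of Gfap from the rod region lost its call without PBS eye 1 (0.0938) [5.57e-08 to 0.0938]. The difference of Gfap from cluster 7 lost its call without hydrogel eye 2 (0.490) [6.76e-20 to 0.490]. The difference of Gfap from cluster 14 lost its call without PBS eye 1 (1) and PBS eye 2 (0.948) [2.40e-06 to 1]. The difference of Lyz2 from cluster 14 lost its call without hydrogel eye 2 (0.377), PBS eye 1 (1) and PBS eye 2 (0.391) [7.78e-04 to 1].

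Shares of spots were compared only for the regions whose leading genes had no call between the groups. The bipolar region, led by Gng13, held 4.98 ± 1.09% of hydrogel and 8.37 ± 0.197% of PBS spots (SD, n = 2 eyes per group), the rod region, led by Ppef2, 6.94 ± 0.987% of hydrogel and 8.75 ± 0.647% of PBS spots, and cluster 14, led by Nefh, 1.99 ± 0.352% of hydrogel and 3.22 ± 0.382% of PBS spots. Each share was lower in both hydrogel eyes, with an exact two-sided permutation p of 0.333 for each, the smallest that 4 eyes allow. Numbers of rod spots were 150 and 129 against 145 and 132, so the lower rod share goes with more spots in all in hydrogel eyes (1965 and 2068 against 1574 and 1591). Rod shares of the eyes overlapped with marker genes only (7.48 and 6.77 against 8.26 and 6.91%), with section means removed (8.19 and 7.40 against 9.66 and 8.04%) and with spots of at least 500 genes (3.35 and 0.577 against 2.41 and 4.16%, 62 and 11 against 35 and 61 spots). With section means removed, an alternative added after the data were seen, the differences went from -3.39 to -1.96% (bipolar), -1.23 to -0.786% (cluster 14) and -1.82 to -1.05% (rod). With marker genes only, the rod difference was -0.461% and that of cluster 14 -0.720%. Leading genes were called in the RGC (33 of 65), RPE (7 of 50) and myelin (6 of 50) regions and in cluster 7 (1 of 50), so their shares were not compared. The difference of cluster 14 was -0.829% without PBS eye 2 section 1 and -1.69% without PBS eye 2 section 2. The share depends on where an eye was cut. Rod genes were also among the leading genes of cluster 15 (nearly all PBS) and the fibroblast and sclera group (nearly all hydrogel), so the rod region holds only part of the rod RNA.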

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

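The tests of free RNA and of Hba-a3 came after the results were seen. Dixon's test, the interaction counts and the count of other splits were chosen before.

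Of 75 sets of 4 sections examined, 4 had a section far from the other 3 by Dixon's test, and chance gives about 1 in 20. The mitochondrial share of the first section of hydrogel eye 2 was 5.20%, where the other hydrogel sections had 5.82 to 5.89%. On the scale of log2(CPM + 1), Acod1 was 0.325 in the first section of PBS eye 2 and 0 in the other PBS sections, Cxcl9 was 2.15 in the second section of PBS eye 1 against 1.71 to 1.75, and Crygb was 4.23 in the first section of hydrogel eye 1 against 1.43 to 1.88 in the other hydrogel sections.

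Interactions of the RGC region with others gave 136 (RPE), 29 (bipolar), 39 and 107 (clusters 14 and 7), 108 (myelin) and 3 (rod) genes. Its clusters 4 and 16 could add to these. Of the hydrogel spots, 15.7% fell in cluster 1 (Ubd, Cxcl10), 13.9% in cluster 3 (Ccl21, Aqp1), 13.8% in the fibroblast and sclera group (Chad, Cilp2), 6.92% in cluster 12 (Fcgbp, Gp2), 3.87% in cluster 10 (Defb14, Sprr1a), 3.05% in cluster 8 (Npvf, Col9a1) and 2.55% in cluster 13 (Lgals7, Krt15). Of the PBS spots, 0.158% fell in the fibroblast and sclera group, 0.0632% in cluster 13 and none in the other 5.

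Immune genes rose in each tested region, and free RNA from spots outside the tested regions could add them. Free RNA at the rate of cluster 1 would put a list's called members near the percent at which that cluster's leading genes stand. Taken of the highest level in a cluster outside the tested regions, it was 6.71% and 8.22% in the 2 hydrogel eyes. In the lower of the eyes the median of the complement genes in the RGC region was 2.21 times that percent, of the reactive gliosis genes 2.33 times and of the MHC class II genes 1.41 times, and the 2 eyes differed by too much to decide. The genes furthest above it in the lower of their eyes were Gfap (181% and 772%), Ednrb (96.2% and 668%), Ctss (85.1% and 54.2%), Mt1 (47.7% and 55.1%), Cebpd (37.0% and 63.5%) and Cp (85.5% and 33.4%) of their highest outside level. The lymphocyte genes, at 1.06 times, are consistent with free RNA. An entry of immune cells, whether with the hydrogel itself or with raised pressure, stays open as well and was not tested.

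Some lens and surface genes fell in retinal regions, where free RNA that follows the whole section may carry them. For the surface epithelium genes, 17 calls of 5 genes in regions differed from the whole-section fold by a median of -0.160 log2 (quartiles -0.27 to -0.09). Calls in a region pick the larger falls, so all tested members were compared too: 65 folds of 11 genes had quartiles of -0.28 to 0.00539. Both are consistent with free RNA. For the lens genes the median over 34 calls of 10 genes was -1.06 (quartiles -1.57 to -0.72), and all 43 folds had quartiles of -1.5 to -0.12, which leaves it open. How each eye was cut and sectioned stays open too.

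Hba-a3 was nearly absent from both hydrogel eyes. Less blood would lower its near-identical copy Hba-a2 alike, but the log2 ratio of Hba-a3 to Hba-a2 differed between the groups by -6.20, which argues against it. A variant of the animals against the reference could move reads between copies: the highest hydrogel eye held 1.02% of the PBS mean, and it stays open, since a variant can lower the reads of a copy to nearly none. As the labels name no strain, a difference in stock stays open in every comparison, the polymorphic RT1 genes included. An effect of pressure stays open and was not tested.

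The 4 eyes can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 2772 called genes, and 1 of the 3 splits gave as many. The other 2 splits gave 0 and 0 by edgeR, with 26 and 77 genes at an unadjusted p below 0.05 against 5300 for the real split, and 0 and 18 by DESeq2.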

How the results depend on the processing

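Thinning, free RNA removal, the 7 regions at own shares and shares without section means were chosen after the data were seen. The 396 named results had 11347 values in alternatives that tested them. Of these, 9931 kept direction and side of the threshold, 1401 only the direction, and 15 reversed. Where no cause is given below, the cause was not tested.

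Counts of called genes in whole sections, RGC, RPE, bipolar, cluster 14, cluster 7, myelin and rod regions were 2772, 879, 234, 221, 17, 95, 63 and 28. They were 3201, 334, 74, 117, 14, 56, 28 and 16 with DESeq2, 3117, 885, 216, 240, 20, 76, 71 and 24 with library size only, 2969, 862, 234, 194, 20, 95, 60 and 23 with upper quartile factors and 2737, 879, 242, 221, 19, 95, 58 and 28 without genes over 1%. Without a filter they were 3865, 1131, 300, 365, 61, 263, 174 and 55, and with 50 counts in 2 eyes, which tests fewer genes, 2485, 455, 109, 74, 3, 31, 32 and 4. Library size moved the median of all genes in whole sections to -0.21 and upper quartile factors to -0.13, from -0.01.

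Sections as samples gave 6027, 802, 199, 208, 37, 182, 145 and 28, with section number as a replicate block 5544, 760, 183, 203, 30, 159, 123 and 26, and with limma voom and the eye as a random block 4415, 858, 200, 193, 25, 166, 134 and 18. Sections that share a number are not pairs: their differences had r of -0.57 to 0.3 between eyes, across genes that are not independent replicates. Only sections numbered 1 gave 2360, 277, 118, 132, 5, 46, 21 and 9, and only those numbered 2 1294, 418, 114, 75, 6, 26, 33 and 0. In the rod region with sections numbered 2, edgeR called 0 genes and 74 had an unadjusted p below 0.05. Spots with at least 500 genes gave 2695, 854, 230, 223, 18, 95, 68 and 32, and the mean of spots gave 2080, 469, 137, 191, 3, 72, 59 and 12. The 7 regions, summed without the other spots, gave 341 at their own and 648 at equal shares. Thinning, which leaves fewer counts, gave 2721, 754, 145, 160, 8, 73, 37 and 14.

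For the 7 regions, the lower resolution gave 814, no value, 236, 38, 103, 79 and 29, the higher 954, 212, 240, 23, 124, 63 and 24, marker genes only 714, no value, 196, 54, 100, 75 and 18, and section means removed 666, 162, 219, 46, 207, 68 and 65. At the lower resolution and with marker genes only, no cluster was taken for the RPE region, so it has no value. At least 30 spots in each eye left the regions as they were. Free RNA taken off at the corneal rate gave 399, 30, 25, 0, 6, 16 and 0, and free RNA of the Ubd cluster 276, 93, 40, 2, 18, 21 and 14. Beside the 0 calls by edgeR at the corneal rate, 125 genes in cluster 14 and 41 in the rod region had an unadjusted p below 0.05.

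Reversed log2 fold changes (adjusted p) follow. Over-subtraction of free RNA could give some. At equal region shares they were 0.12 (0.732) for Car8, 0.72 (0.0223) for Gfap, 0.51 (0.114) for S100b and 0.17 (0.484) for Cryab, and in the 7 regions at their own shares 0.0906 (0.863) for Car8, 0.29 (0.520) for Gfap and -0.0228 (0.966) for Pdgfra. With free RNA at the corneal rate taken off they were 1.59 (0.347) for Mbp and 1.73 (0.245) for Pmel in the RGC region, 5.64 (0.0254) for Mbp in the RPE region, and 7.24 (0.0393) for Mbp, 1.43 (0.997) for Ttr, 1.48 (0.00698) for Ptgds and -0.21 (0.997) for Gpx1 in the bipolar region. With free RNA of the Ubd cluster taken off it was -0.19 (0.965) for Lyz2 in the myelin region.

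Interactions against the RPE, bipolar, cluster 14, cluster 7, myelin and rod regions gave 136, 29, 39, 107, 108, 3 genes, 123, 14, 3, 89, 136, 3 with 50 counts in 2 region sums and 156, 24, 18, 71, 109, 6 with library size only. The share differences of the bipolar region, cluster 14 and the rod region were -3.39, -1.23, -1.82 percent of spots, -3.64, -0.720, -0.461 with marker genes only, -3.40, -1.02, -1.91 at the lower and -3.16, -1.40, -2.0 at the higher resolution, -1.96, -0.786, -1.05 with section means removed, and -3.70, -1.39, -1.32 with spots of at least 500 genes. The biological coefficients of variation without TMM were 12.1% within eyes and 19.6% between eyes.

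Camera called 25, 26, 19, 17, 13, 18, 14, 11 lists in the 8 comparisons, cameraPR 26, 26, 20, 20, 14, 19, 12, 11, fry 1, 0, 4, 0, 3, 0, 2, 0, and camera with an estimated correlation 0, 0, 0, 0, 0, 0, 0, 0. With the estimated correlation 1, 3, 5, 6, 5, 3, 2, 1 lists had an unadjusted p below 0.05, and the lowest adjusted p was 0.292. In the 7 regions camera called 20 lists at their own and 24 at equal shares, where with an estimated correlation the lowest adjusted p was 0.494. With an eye left out, fits leave 1 eye in a group, which is assumed to vary like the other group.

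Without 1 eye or section the counts of genes ranged over 1137 to 3788 (whole sections), 436 to 1101 (RGC), 156 to 258 (RPE), 126 to 316 (bipolar), 5 to 77 (cluster 14), 38 to 127 (cluster 7), 53 to 134 (myelin), 8 to 37 (rod). Interactions ranged over 54 to 158 (RPE), 29 to 60 (bipolar), 1 to 40 (cluster 14), 88 to 150 (cluster 7), 51 to 141 (myelin), 1 to 11 (rod), lists over 23 to 29 (whole sections), 22 to 27 (RGC), 17 to 20 (RPE), 18 to 20 (bipolar), 12 to 15 (cluster 14), 14 to 20 (cluster 7), 9 to 14 (myelin), 11 to 14 (rod), and shares over -3.77 to -2.98 (bipolar), -1.69 to -0.829 (cluster 14), -2.08 to -1.58 (rod).

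In simulated data 2-fold and 4-fold changes were called for 13.4 and 69.7% of the changed genes in cluster 14, 17.9 and 74.2% in the rod region and 46.3 and 83.3% in the myelin region.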

Other observations

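No hypothesis of this part was tested. Some clusters found in 1 treatment shared leading genes with a cluster of the other. Npvf, Col9a1 and Slc26a4 led cluster 8, with 3.05% of the hydrogel spots, and cluster 18, with 4.58% of the PBS spots. Krt15, Wfdc21, Krt13 and Serpinb10 were among the leading genes of cluster 13, with 2.55% of the hydrogel spots, and of cluster 17, with 5.84% of the PBS spots. The surface epithelium group, led by Slurp1 and Krt12, held 4.55% of the PBS and none of the hydrogel spots, while cluster 10, led by Defb14 and Sprr1a, held 3.87% of the hydrogel and none of the PBS spots, with 5 surface epithelium genes among its 50 leading ones.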
